A study of Homo sapiens with 4 samples.

How the data were processed

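Total RNA from the Jurkat line was compared between 2 samples that received a hairpin against TRIB2 and 2 that received a hairpin against green fluorescent protein. Groups and replicate numbers were taken from the sample titles, and the labels call the samples biological duplicates, so p-values measure the spread between duplicate cultures of each group. Per the labels, RNA was biotin-labelled by the standard Affymetrix procedure. The values are linear signal intensities per probe set, as deposited by the authors. The method that summarised probes and normalised arrays is not given in the sources used here. From the values, the array medians were alike (38.71 to 39.6) and the sorted columns differed; no quantile normalisation was added in the main comparison. Between 2.50% and 2.77% of probe sets on an array had a value of exactly 1. No detection calls were used, and the number of arrays limits the precision.

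Each array had 54675 probe sets, of which 62 were control probe sets, some of which are not reported here. The platform annotation gave 41091 probe sets with 1 gene, 1801 with several and 11721 without a named gene. Only probe sets with 1 gene entered the gene tests, and symbols were updated by gene number through a RefSeq annotation (GRCh38.p14), which matched 19735 of 19777 genes. No coordinates are given because no genome build is tied to the array. Signals were transformed as log2 of the value plus 1, and all log2 differences and folds are shTRIB2 against shGFP on that scale, which understates the change of genes with low signal. Group means and SDs are of the deposited signals. Each gene was represented by the probe set with the highest mean log2 signal over the 4 arrays. Genes were tested where that mean reached the median of all probe sets other than controls, a signal of 37.8, which left 12126 genes and put 7651 below. Of the called genes, 2135 had several probe sets above that level, and for 1371 (64.2%) these all moved in the same direction; for AKT2, BCL11A, BCL11B, ITGB2, XIAP, ATF5 and EGLN1, named below, 1 of several moved the other way.

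Tests were made with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8: lmFit with group as the only term, eBayes, two-sided moderated statistics with 2 residual and 3.75 total degrees of freedom, and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and adjusted over the 34 of 38 lists with at least 5 tested genes; 4 lists passed, 9 had an unadjusted p under 0.05, and with an estimated correlation 0 passed at either level, the smallest adjusted p being 0.783. With an estimated correlation camera tests each list on the 2 residual degrees of freedom, where even a large shift can hardly pass. Its p-values therefore do not show whether correlation between genes explains a shift. fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes, called 17 lists. Of these, 13 had not passed in camera. Among the 13 were immediate early and ERK feedback genes (fry adjusted p = 0.00502), cholesterol synthesis (0.0114), anti-apoptotic genes (0.0135) and pro-apoptotic genes (0.0232). Where a count is said to be adjusted over the list alone, Benjamini-Hochberg was applied within the list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

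The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule named TRIB2, the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap, up to 4 members with the smallest p of each list described with the list's direction first, and all tested members of the TAL1 complex; uncharacterised loci were skipped. RUNX1, a member of the complex, was not tested because its probe sets were annotated to several genes. The alternatives were the replicate number as a block, leaving out each array, quantile and cyclic loess normalisation, no level filter or the 75th percentile, the mean of all probe sets, a floor at the 25th percentile, a variance trend with robust estimation, tests per probe set, an adjusted p of 0.1, a minimum fold of 1.2 with treat, an estimated correlation, fry, and the other TRIB2 probe set. Scaling to the hybridisation controls, leaving out probe sets at exactly 1, the TAL1 target list without TRIB2, and the variance trend combined with no level filter or with a missing shTRIB2 array were added after the data were seen.

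The procedure was tested on simulated data for this comparison, with 12126 genes and 2 arrays per group. With 200 changed genes it recovered 10%, 71.5% and 93.2% of those changed by 0.5, 1 and 2 on the log2 scale, with 5.60% false calls. With 3786 changed genes it recovered 81.5%, 94.5% and 98.5%, with 3.66% false calls. The changed genes were given only these sizes, and the spread was drawn without regard to signal level. Called genes in the data had a median size of 0.43 and a smallest of 0.19 on the log2 scale. The shares recovered and the false calls therefore do not carry over to the 3786 genes called in the data. A list of 20 genes shifted by 0.3 was called in 10 of 10 draws, and 0 of 330 unshifted lists were called by camera in the same draws. In these draws the genes varied independently and only the genes of that list were changed. The draws therefore do not show how camera behaves with correlated genes or with many changed genes.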

Results

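Gene expression was measured in Jurkat cells, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line, after lentiviral delivery of a short hairpin RNA against TRIB2 (shTRIB2) or against green fluorescent protein as a control (shGFP). TRIB2 encodes a pseudokinase of the tribbles family. RNA was collected 72 hours after infection, with puromycin selection of the infected cells, from biological duplicates of each group, and each of the 4 RNA samples was hybridised to an Affymetrix array of 54675 probe sets. The median deposited signal was 38.98 and 38.99 on the shGFP arrays and 38.71 and 39.6 on the shTRIB2 arrays. Across probe sets the log2 signals of the shGFP duplicates correlated with r = 0.973 and those of the shTRIB2 duplicates with r = 0.976, while pairs of arrays from different groups gave 0.968 to 0.970. Probe sets are not independent replicates. The number of arrays, 2 per group, limits the precision of every value below.

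TRIB2 itself was lower in the knockdown. Its signal was 3225 ± 6.18 in shGFP and 757 ± 27.0 in shTRIB2 (SD, n = 2 each), a 4.26-fold decrease that left 23.5% of the control signal. The log2 difference was -2.09 with a standard error of 0.05 (limma, adjusted p = 0.0069). The other TRIB2 probe set gave 1152 ± 66.4 and 255 ± 1.46 (SD, n = 2 each), a 4.51-fold decrease. Both shTRIB2 arrays lay below both shGFP arrays on each probe set. Without shTRIB2 replicate 1 or 2 TRIB2 stood at -2.13 and -2.05 and did not pass (limma, adjusted p = 0.0765 and 0.0698), nor did it with no level filter (0.0702).

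The comparison of shTRIB2 with shGFP asked which transcripts differ after loss of TRIB2. Among the genes that rose most were GPNMB, a transmembrane glycoprotein, by 7.33-fold (log2 difference 2.87 ± 0.17, SE), and FA2H, a fatty acid hydroxylase, by 3.90-fold (1.96 ± 0.11). TNFRSF4, the costimulatory receptor OX40, rose 3.76-fold, the Notch ligand JAG1 3.64-fold, the homing receptor CCR7 3.56-fold and the decoy receptor IL1R2 3.29-fold. NKG7, a protein of cytotoxic granules, rose 3.54-fold, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.44-fold (log2 difference 1.78 ± 0.21, SE). OSCP1 (3.55-fold), EPB41L4B (3.49-fold), ALDH8A1 (3.27-fold) and the cytidine deaminase APOBEC3B (3.22-fold) completed the 12 largest increases. These 12 genes had low control signals, from 24.0 for APOBEC3B to 88.1 for OSCP1, and their adjusted p-values ran from 0.0069 to 0.0143 (limma, n = 2 per group). The mean control signals of APOBEC3B, FA2H, CDKN1A, CCR7 and ALDH8A1 lay below the level filter of 37.8. These genes passed it through their shTRIB2 signal, so the sizes and ranks of their changes are uncertain. On single control arrays CCR7 (29.5 and 38.0) and ALDH8A1 (38.0 and 32.2) lay on both sides of that level. GPNMB had control signals on both sides of that level, 33.1 and 45.3, so the size and rank of its change are uncertain too.

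The largest decrease was that of EPAS1, a subunit of the hypoxia-inducible transcription factors, with a log2 difference of -2.33 ± 0.08 (SE), or 5.02-fold. PFN2, an actin-binding profilin, was 4.95-fold lower (-2.31 ± 0.07), ENTREP3 4.78-fold lower and the sodium channel gene SCN3A 4.26-fold lower. CD69, a marker of early T cell activation, was 3.90-fold lower, SKIL, a repressor of TGF-beta signalling, 3.69-fold lower and the transcriptional regulator ARID5B 3.65-fold lower. The G protein subunit gene GNG2 (3.56-fold), the interleukin receptor gene IL7R (3.53-fold), the kinase gene UHMK1 (3.42-fold) and CRLF3 (3.42-fold) followed. Most of these started from high control signals, such as 4049 ± 23.0 for UHMK1, 2928 ± 144 for GNG2 and 2154 ± 5.76 for ENTREP3 (SD, n = 2). Their adjusted p-values lay between 0.0069 and 0.0083 (limma).

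**Figure D1:**
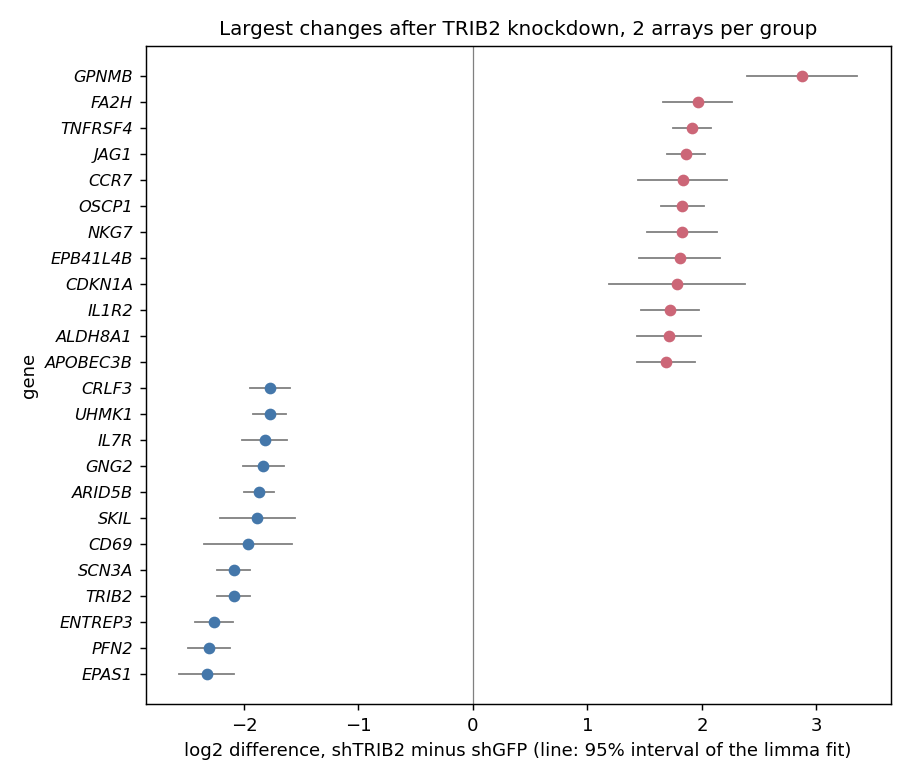
Log2 difference in signal (x axis, shTRIB2 minus shGFP, on log2 of signal plus 1) for the 12 genes with the largest increase and the 12 with the largest decrease (y axis), 2 arrays per group; points are limma estimates and lines their 95% intervals. GPNMB stands highest at 2.87 and EPAS1 lowest at -2.33.

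In total 3786 of 12126 tested genes, or 31.2%, passed an adjusted p of 0.05 (limma), 1721 higher and 2065 lower in shTRIB2, with a median size of 1.35-fold among them. At an unadjusted p of 0.05 the number was 5560. The groups did not overlap for 71.5% of tested genes, where chance alone gives 33.3%. A change of at least 2-fold without overlap was seen for 246 genes, 101 higher and 145 lower, and 225 of these also passed the test. That number of 246 became 919 with no level filter, 134 with the 75th percentile filter and 144 with the mean of all probe sets. The number of called genes depended on the settings and on single arrays. It was 6305 with a test per probe set, 1886 with the mean of all probe sets and 805 with a minimum fold of 1.2 (treat). It was 0 of 19777 with no level filter (limma, 5301 at an unadjusted p under 0.05, 5093 called with a variance trend and robust estimation). It was 1067 without shGFP replicate 1, 1859 without shGFP replicate 2 and 0 without either shTRIB2 array. Without either shTRIB2 array 3968 and 4085 genes had an unadjusted p under 0.05 and limma with a variance trend and robust estimation called 4561 and 4583. The share of lower genes depended on the scale between arrays. It was 54.5% on the deposited scale and 14.4%, with 2730 genes higher and 460 lower, when arrays were scaled to their hybridisation control transcripts. This alternative was chosen after the data were seen and moved the median of all tested genes from -0.013 to 0.23. The hybridisation controls differed by a median of -0.24 between the groups and the labelling controls by -0.07. On the arrays' own control probe sets, 28S ribosomal RNA was 2.26-fold and 2.52-fold higher in shTRIB2. The log2 ratio of the 5' to the 3' probe set of ACTB went from -1.32 ± 0.10 to -1.68 ± 0.13 (SD, n = 2), with the 3' probe set near the top of the scale at 11787 and 11446.

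Targets of the TAL1 complex, the transcription factor complex that drives a major class of T-ALL, were lower as a group. Of 18 tested targets, 12 fell and none rose (13 lower adjusted over the list alone), with a median log2 difference of -0.42 (camera, adjusted p = 9.0e-05). The list includes TRIB2; without it the median was -0.42 and the adjusted p 0.000419. The call was lost when the correlation between genes was estimated from the 4 arrays (adjusted p = 0.783 with an estimated correlation), as it was for every list. With 2 residual degrees of freedom that version could hardly call any list, so it does not decide whether correlation explains the shift. ARID5B fell from 2275 ± 22.8 to 623 ± 13.1 (SD, n = 2). GIMAP2, a GTPase of lymphocytes, fell 2.49-fold and ALDH1A2, an enzyme of retinoic acid synthesis, fell 2.21-fold. ALDH1A2 had 2 probe sets above the level filter, and the other was higher in shTRIB2. Among the 7 tested members of the complex itself, GATA3 fell 1.47-fold (log2 difference -0.56 ± 0.05, SE), TAL1 1.39-fold (-0.48 ± 0.05), MYB 1.31-fold (-0.39 ± 0.05) and TCF12 1.15-fold (-0.20 ± 0.04), with limma adjusted p-values from 0.0096 to 0.0421. LDB1 (-0.26, adjusted p = 0.055), TCF3 (0.08) and LMO1 (0.05) did not pass in limma, and the members as a list did not pass either (median -0.26, camera adjusted p = 0.136, 5 lower adjusted over the list alone). With the mean of all its probe sets TAL1 stood at 0.047 and no longer passed (limma, adjusted p = 0.913); of its 3 probe sets above the level filter, 1 was higher in shTRIB2. On the scale of the hybridisation controls TCF12 stood at 0.039 (limma, adjusted p = 0.890) and the median of the targets at -0.18.

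**Figure D2:**
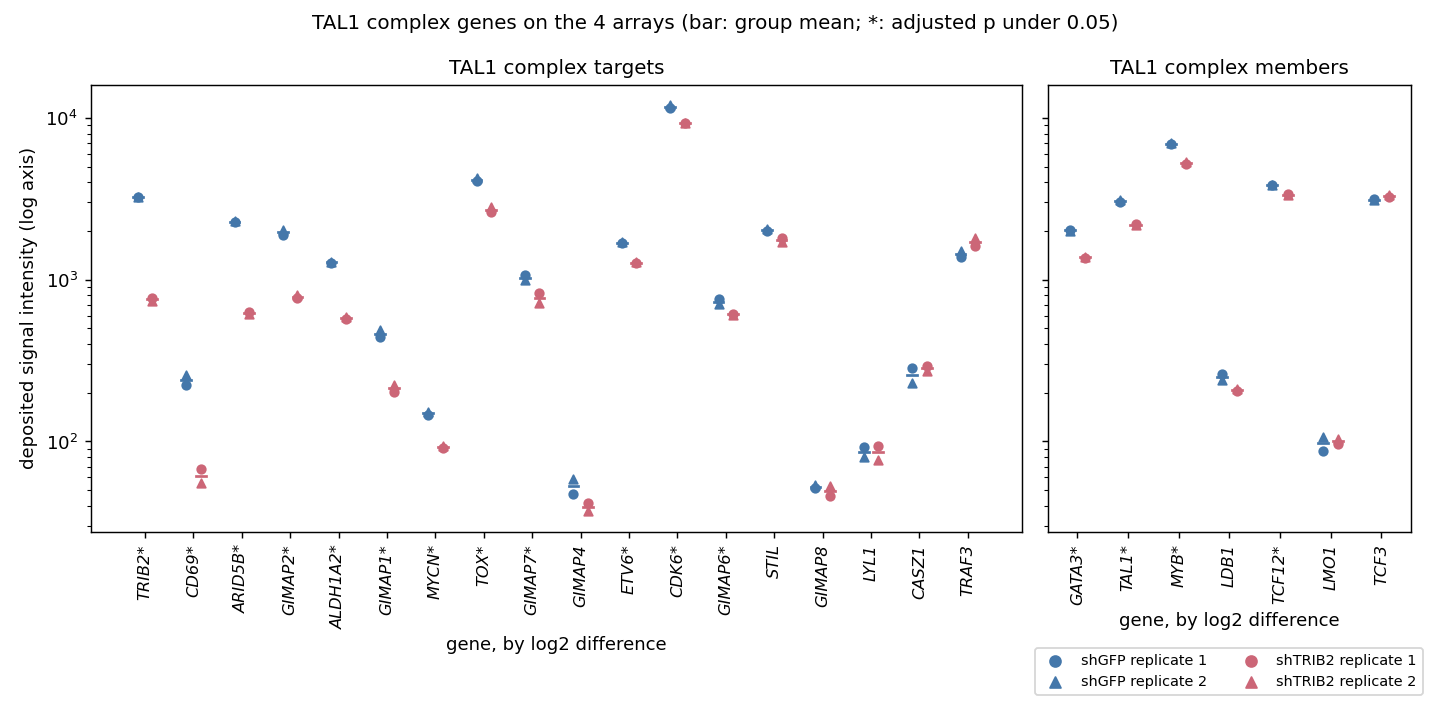
Deposited signal intensity on a log axis (y) for each tested target (left) and member (right) of the TAL1 complex (x), with 1 symbol per array and a bar at each group mean; asterisks mark genes with a limma adjusted p under 0.05. For TRIB2, ARID5B, GIMAP2, ALDH1A2 and CD69 the 2 shTRIB2 arrays lie well below the 2 shGFP arrays.

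Genes of the proteasome, the complex that breaks down tagged proteins, were higher as a group. Of 27 tested proteasome subunits, 15 rose and none fell (17 higher adjusted over the list alone), all 27 differences were above 0, and the median was 0.26 (camera, adjusted p = 8.5e-07; adjusted p = 0.783 with an estimated correlation). The list does not hold every gene with such a symbol. Among all tested genes, 6 of 11 with the stem PSMB rose and 1 fell, and 2 of 8 with the stem PSMA rose and 1 fell. PSMD12 rose 1.80-fold (log2 difference 0.85 ± 0.05, SE), PSMC1 1.47-fold, PSMD11 1.39-fold and PSMD4 1.31-fold; the other PSMD11 probe set above the level filter was lower. Of 19 endoplasmic reticulum (ER) chaperones and genes of the unfolded protein response (UPR), 8 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 0.16 (camera, adjusted p = 0.033; adjusted p = 0.783 with an estimated correlation). HSPA5, the main ER chaperone BiP, rose 1.59-fold, HSP90B1 1.63-fold and HYOU1 1.37-fold, whereas SEL1L, a component of ER-associated degradation, fell 1.47-fold by its brightest probe set and was higher in shTRIB2 by the other 2 above the level filter. The ER list did not pass without shGFP replicate 1 (adjusted p = 0.097), without shTRIB2 replicate 1 (0.0657), with the mean of all probe sets (0.0541) or on the scale of the hybridisation controls (0.196), within a range over the settings of camera of 0.0175 to 0.783. Of 11 heat shock genes 4 rose and none fell, also 4 adjusted over the list alone, among them HSPA4L by 2.00-fold and DNAJB1 by 1.44-fold, but the list did not pass (median 0.15, camera adjusted p = 0.0876). Cytosolic ribosomal proteins lie near the top of the scale, with control signals such as 13300.5 for RPL37 and 11802 for RPS4X, where a change can show little. They gave 0 of 37 genes past an adjusted p of 0.05 in limma, over all genes and adjusted over the list alone (median 0.018, camera adjusted p = 0.627, fry adjusted p = 0.725, camera unadjusted p = 0.378). This list too does not hold every gene with such a symbol. Among all tested genes, 0 of 40 with the stem RPL rose and 2 fell, and 1 of 33 with the stem RPS rose and 1 fell.

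Genes of the T cell receptor complex and its signalling were mostly lower. Of 23 tested, 10 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.23 (camera, adjusted p = 0.0474; adjusted p = 0.783 with an estimated correlation). The costimulatory receptor gene CD28 fell 1.79-fold, the phospholipase gene PLCG1 1.45-fold and the adhesion receptor gene CD2 1.42-fold, and PTPN22, a phosphatase that restrains T cell receptor signalling, rose 1.54-fold. With the mean of its probe sets CD28 stood at 0.13 and did not pass (limma, adjusted p = 0.425). This list did not pass without shGFP replicate 1 (adjusted p = 0.0985), without shTRIB2 replicate 1 (0.0657) or 2 (0.094), with cyclic loess normalisation (0.0574), with a stricter level filter (0.120) or on the scale of the hybridisation controls (0.243, median 0.016), within a range over the settings of camera of 0.0175 to 0.783. Of 22 thymocyte stage genes 6 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.17, camera adjusted p = 0.136). The transcription factor genes BCL11A, GATA3 and BCL11B fell 1.67-fold, 1.47-fold and 1.45-fold, and the coreceptor gene CD8B rose 2.80-fold. Of 8 activated T cell genes 2 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 0.627), among them CD69 and GZMA, a granzyme gene that fell 2.13-fold, and TNFRSF4. Of 13 lymphocyte trafficking genes 6 fell and 2 rose, the same numbers adjusted over the list alone (median -0.26, camera adjusted p = 0.556), with the integrin genes ITGA4 and ITGB2 1.59-fold and 1.33-fold lower and CCR7 higher.

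Genes of cell death and of growth control changed in both directions, and none of these lists passed the camera test. Of 21 pro-apoptotic genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.12, adjusted p = 0.233). PMAIP1, which encodes NOXA, rose 1.79-fold, the death receptor gene FAS 1.78-fold and BID 1.21-fold, while BNIP3L fell 1.78-fold. Of 7 anti-apoptotic genes 3 fell and none rose, also 3 adjusted over the list alone (median -0.07, adjusted p = 0.312). The caspase inhibitor XIAP fell 2.44-fold, BCL2L1, which encodes BCL-XL, 1.31-fold and BIRC2 1.29-fold, while the other BCL2L1 probe set above the level filter was higher. Of 17 immediate early and ERK feedback genes 6 fell and 2 rose, the same numbers adjusted over the list alone (median -0.33, adjusted p = 0.162), with DUSP6, a phosphatase that inactivates ERK, 2.18-fold lower and SPRED2 2.04-fold lower. Of 9 tribbles and MAPK partners, TRIB2 and CDC25C fell and AKT2 rose, also when adjusted over the list alone (median 0.022, mean -0.22, adjusted p = 0.965, tested direction lower). The list includes the knocked-down TRIB2 (-2.09), which pulls the mean down, and 6 of the 9 differences lay above 0. CDC25C fell 1.15-fold and stood at 0.046 on the scale of the hybridisation controls (limma, adjusted p = 0.871). Of 18 p53 targets 7 rose and 6 fell (7 and 7 adjusted over the list alone; median 0.11, adjusted p = 0.718), with PMAIP1 and FAS higher and SESN1 and MDM2 1.52-fold and 1.36-fold lower; the mean of its probe sets put MDM2 at 0.10 (limma, adjusted p = 0.676). Of 10 cell cycle inhibitors 4 rose and 3 fell, as when adjusted over the list alone (median 0.0090, adjusted p = 0.822). CDKN1C rose 1.81-fold and CDKN2D 1.38-fold, CDKN1B, which encodes p27, fell 1.51-fold and CCNG2 1.60-fold, and with the mean of its probe sets CDKN2D stood at -0.31 (limma, adjusted p = 0.400). Of 34 mitosis genes 8 fell and 1 rose (5 and 1 adjusted over the list alone; median 0.021, mean -0.09, adjusted p = 0.899, tested direction lower), among them the kinase gene AURKA, 2.15-fold lower, and TPX2, 1.64-fold lower. Of 39 DNA replication and E2F genes 11 fell and 4 rose (12 and 6 adjusted over the list alone; median -0.06, adjusted p = 0.386), with the polymerase gene POLE 1.46-fold and the clamp loader gene RFC5 1.39-fold lower. Of 23 FOXO targets 8 fell and 4 rose (8 and 5 adjusted over the list alone; median -0.10, adjusted p = 0.606), FOXO3 itself falling 1.88-fold and KLF2 rising 1.85-fold. NOTCH1 targets were divided, with 5 of 14 higher and 5 lower, also adjusted over the list alone (median 0.07, adjusted p = 0.983), such as IGF1R, 1.80-fold higher, and IL7R, lower.

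**Figure D3:**
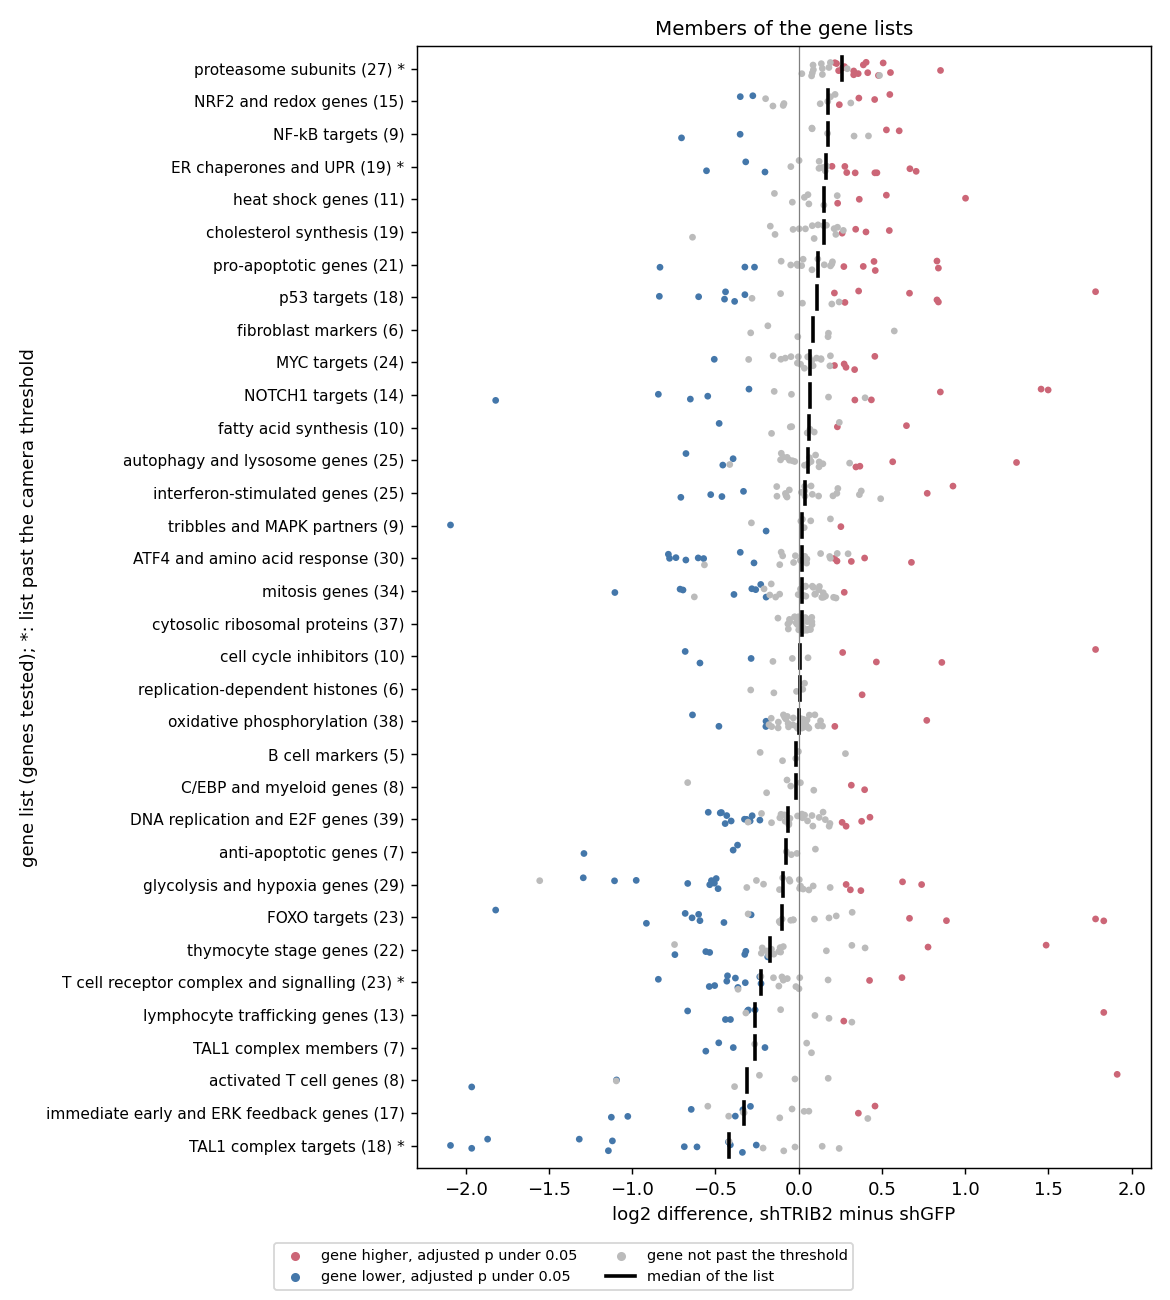
Log2 difference (x axis, shTRIB2 minus shGFP) of each tested member of the 34 tested gene lists (y axis, number of genes tested in brackets); red and blue points passed a limma adjusted p of 0.05, grey points did not, black bars are list medians and asterisks mark the 4 lists past camera's threshold. TAL1 complex targets have the lowest median, -0.42, and proteasome subunits the highest, 0.26.

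Few markers of other cell types passed the test. None of 5 tested B cell markers, 2 myeloid markers, 1 erythroid marker, 3 epithelial markers or 6 fibroblast markers passed in limma, over all genes or adjusted over the list alone, although the B cell marker BLK, the epithelial marker CLDN3 and the fibroblast marker FN1 passed as higher on the scale of the hybridisation controls. That fit took the spread as common to all genes. For CLDN3 the groups overlapped, with deposited signals of 31.5 and 90.5 in shGFP and 70.8 and 86.9 in shTRIB2. The 2 of these marker lists large enough for camera, B cell and fibroblast markers, had medians of -0.017 and 0.086 (unadjusted p = 0.908 and 0.429, adjusted p = 0.965 and 0.663; fry adjusted p = 0.918 and 0.410). Of 3 NK cell markers NKG7 rose, as above, also when adjusted over the list alone, and KIR2DL3 (-0.27) and NCR1 (-0.28) did not pass.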

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

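All tests in this part were chosen after the result they address was seen.

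Control probe sets outside the gene comparison differed between the groups. The 2 probe sets of 28S ribosomal RNA above the level filter were higher in shTRIB2 by 1.18 and 1.33 on the log2 scale (limma, adjusted p = 0.0121 and 0.0124), from 2315 ± 73.2 to 5233 ± 29.2 and from 2308 ± 241 to 5804 ± 91.5 (SD, n = 2). The 3 probe sets of 18S ribosomal RNA were higher by 0.44, 0.68 and 0.46 (limma, adjusted p = 0.0375, 0.0255 and 0.0186).

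The values argue against a difference in scale between arrays as the source of the higher ribosomal RNA signal. The 14 hybridisation control probe sets of medium signal were all lower in shTRIB2, with a median of -0.24 and a highest value of -0.014. Of 24 labelling control probe sets of medium signal 15 were lower, with a median of -0.07 and a range of -0.32 to 0.37. Lower RNA integrity in shTRIB2 may contribute and stays open. The 5' to 3' ratio of ACTB differed by -0.36 (log2, shTRIB2 minus shGFP). Its 5', middle and 3' probe sets differed by -0.40, -0.21 and -0.04, so the fall was larger towards the 5' end. Their control signals rose in the same order, 4725, 8967 and 11787. The 3' probe set of ACTB (11787 and 11446) and the probe sets of GAPDH (ratio -0.02) lie near the top of the scale, so a lower level of ACTB could give the same ratio. A higher content of ribosomal RNA after loss of TRIB2 is a possible biological explanation, and it was not tested.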

How the results depend on the processing

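The scaling to hybridisation controls and the variance trend combined with another change were chosen after the data were seen. The 3786 called genes (1721 higher, 2065 lower) became 2368 (1035 and 1333) with the replicate block, 2217 of them shared. The numbers were not taken as paired, since deviations of same-numbered arrays correlated at 0.0476 over 2 pairs. The count was 1886 (936 and 950) with the mean of all probe sets, 6305 (3011 and 3294) per probe set and 805 (319 and 486) with treat. With no level filter limma called 0 (0 higher, 0 lower) of 19777 genes, with 5301 at an unadjusted p under 0.05 and 5093 called with a variance trend and robust estimation. Without a single array, where the lone array is assumed to vary like the other group, it ranged from 0 to 1859 (higher 0 to 881, lower 0 to 978), with 3968 to 5037 at an unadjusted p under 0.05. The 0 came from leaving out either shTRIB2 array; there 4561 and 4583 were called with a variance trend, which treats the spread as common to all genes of a level. Scaling to the hybridisation controls gave 2730 higher and 460 lower, 2096 shared in all, in a fit that took the spread as common to all genes; the control signals differed by 0.18 between the shGFP duplicates themselves. Quantile and cyclic loess normalisation turned the majority, with 45.2% and 46.7% of calls lower against 54.5%.

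TRIB2 fell under every setting; it no longer passed with no level filter (-2.09, adjusted p = 0.0702) or without a shTRIB2 array (range over left-out arrays -2.13 to -2.05, highest adjusted p 0.0765). The 246 genes past 2-fold became 919 with no level filter, 134 with the 75th percentile filter, as more or fewer genes were tested, and 144 with the mean of all probe sets, where the values also changed. The 4 called lists became 2 with the replicate block (ER chaperones 0.0525, T cell receptor 0.0626), 0 of 34 with an estimated correlation in camera (0 at an unadjusted p under 0.05), 17 with fry, 2 on the scale of the hybridisation controls and 2 to 4 without a single array; TAL1 complex targets and proteasome subunits lost their call with the estimated correlation alone. Directions turned for TAL1 (0.047), CD28 (0.13), MDM2 (0.10), CDKN2D (-0.31), CHORDC1 (-0.23) and RPL37 (-0.43, adjusted p = 0.0302) with the mean of all probe sets, which joins probe sets that disagree, and for TCF12 (0.039) and CDC25C (0.046) on the scale of the hybridisation controls. Of the 125 called named genes other than TRIB2, 109 stayed called with the replicate block, 122 and 121 with quantile and loess normalisation, 86 on the scale of the hybridisation controls, 73 of 116 with the mean of all probe sets, 74 and 90 without shGFP replicate 1 and 2, and in limma 0 with no level filter or without either shTRIB2 array. Genes near the level filter have low signals, where the log2 scale with 1 added understates folds.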

Other observations

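The gene families below, zinc finger genes included, were chosen after their values were seen, the tests on random lists after the shifts they address were seen, and the split of the arrays was tested after the result was known.

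Some genes of families outside the lists also changed. All 5 tested HLA class I genes fell, HLA-E by 1.94-fold, HLA-B 1.82-fold, HLA-F 1.78-fold, HLA-G 1.65-fold and HLA-C 1.47-fold (limma, adjusted p from 0.0076 to 0.0149). Probe sets of such similar genes can share target. All 5 lay below 0 with quantile, cyclic loess and hybridisation control scaling, and 4 passed on the last. Of 7 metallothionein genes 5 rose, among them MT1X by 1.57-fold and MT1H by 1.52-fold. Their probe sets can share target too: MT1X, MT1H and MT1HL1 had similar signals (shGFP 900, 891 and 903, shTRIB2 1415, 1358 and 1336). The 5 may therefore not be separate observations. Of 4 APOBEC3 genes APOBEC3B and APOBEC3G rose, the latter 2.38-fold, and with the mean of all probe sets 1 of the 4 passed. Of 8 TMED genes, which encode cargo receptors between the ER and the Golgi, 5 rose, TMED5 by 2.76-fold, but 2 passed with the mean of all probe sets. Without shGFP replicate 1 only 2 genes each of the HLA, metallothionein and TMED families passed, without shGFP replicate 2 it was 2 metallothionein and 3 TMED genes, and without either shTRIB2 array none did, as for all genes. Among 204 families of at least 8 tested genes that share a symbol stem, camera called 7: PSMD, PSMB, TMED, MT and THAP higher and ZNF and ZFP lower, with adjusted p from 0.000473 to 0.0453 (adjusted p = 0.98 with an estimated correlation).

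The remaining lists did not pass in camera. Of 19 cholesterol synthesis genes 4 rose and none fell, the same adjusted over the list alone (median 0.15, adjusted p = 0.0538), among them MSMO1 by 1.46-fold and ACAT2 by 1.32-fold. Of 10 fatty acid synthesis genes 2 rose and 1 fell, as adjusted over the list alone (median 0.06, adjusted p = 0.583), with ELOVL6 1.57-fold higher and FADS2 1.39-fold lower, the other FADS2 probe set above the level filter being higher. Of 29 glycolysis and hypoxia genes 9 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.10, adjusted p = 0.233), with ALDOC 2.45-fold, ANKRD37 1.97-fold and EGLN1 1.59-fold lower. PKM of that list did not pass (-1.55, limma adjusted p = 0.0566), and its signal on the shGFP arrays was 2332 and 1111. Of 38 oxidative phosphorylation genes 4 fell and 2 rose (2 and 1 adjusted over the list alone; median 0.0015, mean -0.023, adjusted p = 0.899, tested direction lower), with ATP5MC1 1.70-fold higher. Of 30 ATF4 and amino acid response genes 8 fell and 5 rose (8 and 7 adjusted over the list alone; median 0.022, mean -0.087, adjusted p = 0.965, tested direction lower), with ATF5 1.71-fold and ASNS 1.49-fold lower. Of 15 NRF2 and redox genes 4 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.17, adjusted p = 0.355), with GCLM 1.46-fold and TXNRD1 1.37-fold higher. Of 25 autophagy and lysosome genes 4 rose and 3 fell, as adjusted over the list alone (median 0.06, adjusted p = 0.691), with GABARAPL1 2.48-fold higher.

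Of 24 MYC targets 5 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.07, adjusted p = 0.175), with NIP7 1.37-fold higher and CAD 1.42-fold lower. Of 9 NF-kB targets 2 rose and 2 fell (3 and 2 adjusted over the list alone; median 0.17, adjusted p = 0.386): NFKBIA rose 1.52-fold and CD83 1.44-fold, TNFAIP3 fell 1.63-fold and IRF1 1.28-fold. For NFKBIA and IRF1 the other probe set above the level filter moved the opposite way. Of 25 interferon-stimulated genes 4 fell and 2 rose, as adjusted over the list alone (median 0.04, adjusted p = 0.678), with IRF7 1.90-fold higher and RSAD2 1.63-fold lower. Of 8 C/EBP and myeloid genes CEBPB and CEBPG rose, 1.25-fold and 1.32-fold, and none fell, as adjusted over the list alone (median -0.019, mean -0.020, adjusted p = 0.682, tested direction higher). Of 6 replication-dependent histone genes H4C8 rose 1.30-fold and none fell, and adjusted over the list alone limma called 0 (median 0.0058, mean -0.0015, camera unadjusted p = 0.984, adjusted p = 0.984, fry adjusted p = 0.975, tested direction lower). For B cell markers the median and mean lay below 0 and the tested direction was higher. Of 5083 probe sets above the level filter with several genes or without a named gene, 986 changed, 426 higher and 560 lower (limma).

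For the lists with the clearest shifts, a bias that depends on signal level is a candidate explanation. Among 10000 random lists matched on mean signal, 0 had a median as low as the -0.42 of the 17 TAL1 complex targets other than TRIB2 (95% of them between -0.20 and 0.14), and 0 had one as high as the 0.26 of the proteasome subunits (-0.07 to 0.08), which argues against a bias of this kind. These lists describe the 4 arrays and are no test across samples. Direct and indirect effects of TRIB2, or of the hairpin on other transcripts, stay open, since the labels describe a single TRIB2 hairpin group. A difference in RNA quality between the groups could also act on the TAL1 complex targets and the proteasome subunits and was not tested for them.

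Zinc finger genes, many of which encode repressors of transcription, were mostly lower on the deposited scale: of 356 tested ZNF and ZFP genes 97 fell and 19 rose, with a median of -0.14 (adjusted p = 0.98 with an estimated correlation for both stems). A bias that depends on signal level is argued against here too, as 0 of 10000 matched random lists had a median as low (95% between -0.05 and 0.03). On the scale of the hybridisation controls 44 rose, 17 fell and the median was 0.10, while that of all tested genes was 0.23, so the direction turned and the family still lay below the other genes. With quantile and cyclic loess normalisation the family's median was -0.11 and -0.12. With the mean of all probe sets 42 of 308 tested genes fell and 5 rose, with a median of -0.11. Leaving out a single array gave medians from -0.16 to -0.12. A difference in RNA quality could also act on such a family and was not tested for it.

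With 4 arrays there are 3 ways to form equal groups, too few for a share under 0.05. The real grouping gave 3786 genes, 1 of the 3 splits reached that number, and the highest of the others was 0 in limma, with 141 and 113 genes at an unadjusted p under 0.05. Both other splits mixed shGFP and shTRIB2 arrays in each group, so the difference between the real groups entered their spread. They could therefore call few genes, whatever the cause of that difference.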
